A study of Homo sapiens with 6 samples.

How the data were processed

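Messenger RNA was sequenced from 6 HepG2 samples, 3 transfected with a control hairpin plasmid and 3 with a hairpin plasmid against TCTP. Per the labels' protocols, a lipid reagent delivered the plasmids, polyadenylated RNA was selected, and directional libraries were sequenced as paired reads. A harvest at 48 h is named in the labels for quantitative PCR, and the time for sequencing is not given separately. The authors deposited read counts per gene and FPKM values per gene. Per the submitters' processing notes, bcl2fastq, TopHat2 and edgeR were used with the GRCh38 genome, with no versions given. How reads were assigned to genes, the annotation and whether strand was used are not given in the sources used here.

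The deposited count table held 26389 genes, and 26184 genes had deposited FPKM values. For genes above 5 FPKM in every library, the ratio of CPM to FPKM had a median coefficient of variation of 0.276% between libraries. Of the gene identifiers, 98.0% (25870) were found in GENCODE release 29, from which coordinates on GRCh38 were taken. Gene lengths were derived from the ratio of counts to FPKM, wherever a library had at least 5 reads and 0.1 FPKM. A stricter limit used at first left too few genes with a length for a valid check, and its results were replaced. Lengths then covered 99.1% of tested genes, and GC content of the longest GENCODE transcript covered 99.5%. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 13.9 to 85.7), so no pair within a group was found to be 1 library deposited more than once. Pairs across groups were not compared, and this check does not show whether libraries came from separate cultures.

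Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after filterByExpr and TMM normalization, with robust dispersion and group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. CPM values are scaled by the TMM factors. Standard errors of log2 fold changes were derived from the estimate and the quasi-likelihood F statistic. For TPT1 an exact two-sided permutation test of the 6 log2 CPM values was added. In 35 gene lists, 897 of 935 entries were matched to the count table, 11 of them through another symbol. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and with an estimated correlation and fry beside it.

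The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named TPT1, the 10 largest rises and falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, and 8 genes of insulin action and liver metabolism. From each list it named up to 4 members past the threshold, or the 2 with the smallest p where none passed. A result that the rule would name is not reported here. Corrections for gene length and GC content, by a loess curve per library with a span of 0.3, were added after seeing the data.

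The alternatives were RLE and upper quartile normalization, no filter or at least 1 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, dispersion without robust fitting, a test against a fold of 1.5, each library left out in turn, and for TPT1 the sum with its pseudogenes. The pseudogene sum could hardly change TPT1, since the only pseudogene counted, TPT1P4, had 1 read over the 6 libraries. The procedure was tested on simulated data for this comparison, drawn from the real means and library sizes. Genes were drawn independently, with no length trend and no library set apart, so the rates that follow describe a cleaner setting than the real libraries. Of 14048 simulated genes tested, the edgeR test recovered 31.8% of 66 genes changed 1.5-fold, 72.7% of 66 changed 2-fold and 98.5% of 66 changed 4-fold, and 3.70% of its 162 calls were false.

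For the closing section a list of YAP and TEAD target genes was set out from textbook knowledge. The list first run differed by mistake from the one set out. It lacked BIRC5 and held GADD45B and DDAH1, and it gave a one-sided Fisher exact p of 6.0e-05. The list as set out is the one reported. Figures were drawn with matplotlib 3.10.9. Reads along transcripts, splicing and protein levels were not analysed here.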

Results

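RNA-seq read counts were available for 6 libraries of HepG2, a human hepatocellular carcinoma cell line. In 3 libraries the cells had been transfected with a control short hairpin RNA plasmid. In the other 3 the plasmid targeted TCTP, the translationally controlled tumour protein, which is encoded by TPT1. The control libraries held 29969485, 30157731 and 30348435 reads assigned to genes, and the knockdown libraries 30486409, 29735626 and 25427614. Reads were found for 18833 to 21036 genes per library. Knockdown library 3 was the shallowest and stood apart from the rest, with a mean correlation of 0.977 with the other 5 across genes, against 0.986 to 0.987 for the others. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

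The first comparison asked whether the transcript of the targeted gene was lower in the knockdown libraries. TPT1 (ENSG00000133112.16, GRCh38 chromosome 13, 45333471 to 45341370, minus strand) stood at 2371 ± 178 CPM (SD, n = 3; CPM being reads scaled to library size) in control cells and 1799 ± 237 CPM (SD, n = 3) in knockdown cells. The control libraries gave 2575, 2249 and 2290 CPM and the knockdown libraries 2032, 1806 and 1559 CPM, so every knockdown library lay below every control library. The lowest value came from knockdown library 3, which stood apart. Such a separation was not rare, being found for 2432 of 14197 tested genes (17.1%). The estimated level was 75.9% of control, with a log2 fold change of -0.40 (SE 0.17, 95% confidence interval -0.76 to -0.03). The difference did not pass the threshold over all genes (adjusted p = 0.396, edgeR quasi-likelihood test). For this 1 gene, chosen in advance, the unadjusted p of the same edgeR test was 0.034. By that p TPT1 ranked 1214 among the tested genes, of which 1572 had an unadjusted p under 0.05. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow.

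The second comparison asked which genes differed between knockdown and control cells, a question the series title ties to liver metabolism and insulin resistance. Most of the genes that changed were higher after knockdown. ATF3, a stress-induced transcription factor, rose from 30.6 ± 0.616 to 110 ± 7.58 CPM (SD, n = 3 each). GEM, a small GTP-binding protein, rose 6.05-fold from a low level of 0.724 ± 0.155 CPM (SD, n = 3). LOX, which crosslinks collagen, fell from 9.44 ± 2.68 to 3.62 ± 1.35 CPM (SD, n = 3 each), and HPN, a transmembrane serine protease of hepatocytes, fell from 68.8 ± 4.79 to 38.0 ± 3.14 CPM (SD, n = 3 each). Of 14197 tested genes, 200 changed at an adjusted p under 0.05 by the edgeR quasi-likelihood test, 179 of them higher and 21 lower. An at least 2-fold difference was found for 105 of these, 98 higher and 7 lower.

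Among the 10 largest rises, ATF3 had a log2 fold change of 1.84 (SE 0.13, edgeR adjusted p = 1.5e-06) and GEM one of 2.60 (SE 0.27, edgeR adjusted p = 5.1e-05). GH1, the pituitary growth hormone gene, rose from 44.9 ± 5.06 to 164 ± 22.5 CPM (SD, n = 3 each), a log2 fold change of 1.87. The lipoxygenase gene ALOXE3 rose by 2.47 on the log2 scale, the lipid transporter gene MFSD2B by 2.40, the transcription factor gene ETS1 by 2.08 and the serine protease gene HTRA3 by 1.90. The long intergenic RNA RP13-631K18.3 rose by 2.31. The pseudogene IMPDH1P10 rose by 2.27 and the keratin-associated protein gene KRTAP2-3 by 1.87, and both values are uncertain because near-identical copies can share their reads. KRTAP2-3 missed the threshold without control library 2 or 3 or knockdown library 2, with an edgeR adjusted p of up to 0.123, and its log2 fold change was 2.54 without control library 1.

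Among the 10 largest falls, LOX had a log2 fold change of -1.38 (SE 0.27, edgeR adjusted p = 0.0145). The lipocalin gene LCN15 had one of -1.29, CA9, a hypoxia-induced carbonic anhydrase, one of -1.06, and AGXT, the peroxisomal enzyme of glyoxylate removal, one of -0.96. COL2A1 stood at -0.88, HPN at -0.86, the lipid transporter gene ABCA7 at -0.84 and C10orf10 at -0.81. The antisense RNA SLCO4A1-AS1 stood at -1.02 and is uncertain where strand was not used in counting. The annotated microRNA FP671120.4 had the largest estimate, -4.34, from 96, 43 and 107 reads in control and 11, 1 and 0 in knockdown libraries. It was -7.07 without knockdown library 1 and -3.76 without knockdown library 3, and it is uncertain also because near-identical copies exist. Without control library 1 or 2 LOX and CA9 missed the threshold, and CA9 did so without knockdown library 1. AGXT missed it without any 1 control library or knockdown library 2, ABCA7 without any 1 control library or knockdown library 1, C10orf10 without control library 2 or knockdown library 2, and COL2A1 and SLCO4A1-AS1 without any library but knockdown library 3. The highest edgeR adjusted p in these cases was 0.306, for CA9.

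The count changed with 1 library left out, and each such fit has fewer libraries and so less power to pass the threshold. Without control library 1, 2 or 3 it was 90, 79 or 101 genes, without knockdown library 1 or 2 it was 177 or 89, and without knockdown library 3 it was 343. Of the 49 named genes that passed, 22 passed with any 1 library left out, including ATF3, GH1, DUSP1, FOS, JUN, GEM, CYP1A1, HPN and LCN15, and the other 27 missed the threshold without at least 1 library. All 49 kept the sign of their log2 fold change in these fits.

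**Figure D1:**
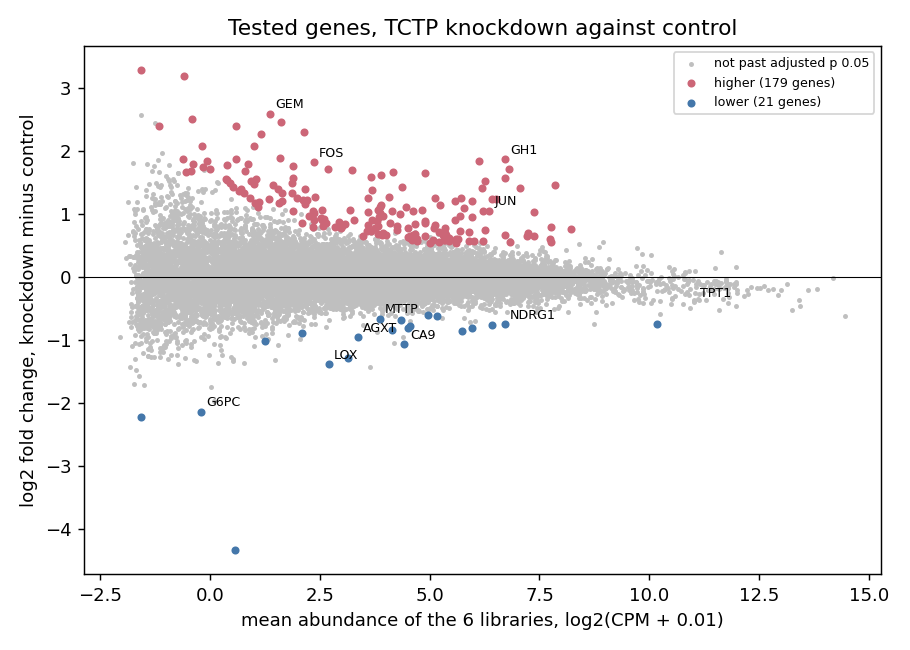
Each point is a tested gene, with the mean abundance of the 6 libraries as log2(CPM + 0.01) on the horizontal axis and the log2 fold change, knockdown minus control, on the vertical axis. The 179 genes called higher are red, the 21 called lower are blue, and grey genes did not pass.

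Genes of the immediate early response, which cells switch on quickly after growth factors or stress, were the list with the largest shift. Of 24 tested members, 14 rose and 0 fell over all genes (19 and 0 adjusted over the list alone), and all 24 had a positive log2 fold change, with a median of 1.05. FOS rose from 2.26 ± 0.423 to 8.03 ± 0.696 CPM, JUN from 53.6 ± 2.24 to 111 ± 3.62 CPM and DUSP1, a phosphatase acting on MAP kinases, from 39.8 ± 3.20 to 115 ± 3.11 CPM (SD, n = 3 each). The list passed limma's camera test (adjusted p = 4.0e-25), with an adjusted p = 0.069 with an estimated correlation. With any 1 library left out, 11 to 17 members rose.

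Of 17 tested targets of NF-kappaB and inflammatory genes 5 rose and 0 fell (9 and 0 adjusted over the list alone), among them the chemokine gene CXCL8 (log2 fold change 1.04), RELB (0.82), TNFAIP3 (0.75) and NFKB2 (0.60), with a camera adjusted p = 1.5e-07 and an adjusted p = 0.069 with an estimated correlation. Of 29 tested p53 targets 5 rose and 0 fell (7 and 0 adjusted over the list alone). GADD45A had a log2 fold change of 1.24, PLK3 of 1.01, the stress-induced SESN2 of 0.70 and the cell cycle inhibitor CDKN1A of 0.65, and the list had a camera adjusted p = 3.6e-05 and an adjusted p = 0.086 with an estimated correlation. With 1 library left out, 0 (without control library 2) to 7 (without knockdown library 3) of the inflammatory genes rose, and 2 (without control library 1 or 2 or knockdown library 2) to 7 (without knockdown library 3) of the p53 targets. The p53 median of 0.25 was 0.14 without knockdown library 3. CXCL8 missed the threshold without control library 2, TNFAIP3 without control library 2 or 3, RELB and SESN2 without control library 1 or 2 or knockdown library 2, and CDKN1A and NFKB2 without any 1 control library or knockdown library 2.

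The histone list holds replication-dependent genes whose messages mostly lack poly(A) tails, while the libraries were poly(A)-selected and the S phase median was -0.11. Of 14 tested histone genes 3 rose and 0 fell (5 and 0 adjusted over the list alone). They were HIST1H4H (1.69), HIST1H2AC (1.26) and HIST1H1C (0.74), whose family members can share reads. HIST1H4H missed the threshold without control library 1 or 2 or knockdown library 2, and HIST1H1C without any library but knockdown library 3, with edgeR adjusted p of up to 0.0772 and 0.197. With 1 library left out 1 (without control library 1 or 2 or knockdown library 2) to 5 (without knockdown library 3) histone genes rose. The histone list had a camera adjusted p = 4.6e-06 and an adjusted p = 0.195 with an estimated correlation. Of 31 tested targets of ATF4 and the integrated stress response 3 rose and 0 fell (4 and 0 adjusted over the list alone). These were ATF3, also in the immediate early list, SESN2, also in the p53 and mTORC1 lists, and PPP1R15A (1.46), which restores translation after stress. The list median was 0.08 (camera adjusted p = 0.0282, and adjusted p = 0.196 with an estimated correlation). The list's camera adjusted p was 0.0509 and 0.133 without control library 1 or 3, and 0.109 and 0.0542 without knockdown library 1 or 2. Of 27 tested BCL2 family and caspase genes 2 rose and 0 fell, both over all genes and adjusted over the list alone. BCL2A1, which protects from cell death, had a log2 fold change of 1.79 and BIK, which promotes it, one of 1.06 (camera adjusted p = 0.0194, and adjusted p = 0.187 with an estimated correlation). The camera adjusted p was 0.131 without control library 1, and 0.0962 and 0.0542 without knockdown library 1 or 2. BCL2A1 missed the threshold without control library 1 (edgeR adjusted p = 0.0581), and BIK without any library but knockdown library 3 (edgeR adjusted p of up to 0.178). Of 27 tested matrix and epithelial-mesenchymal genes 1 rose and 0 fell (4 and 0 adjusted over the list alone). It was CYR61, a secreted matrix protein, at 1.15 (camera adjusted p = 0.00736, and adjusted p = 0.389 with an estimated correlation), and the camera adjusted p was 0.181 without knockdown library 3. The median of this list was 0.18, and 0.29 without knockdown library 1 and 0.05 without knockdown library 3.

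**Figure D2:**
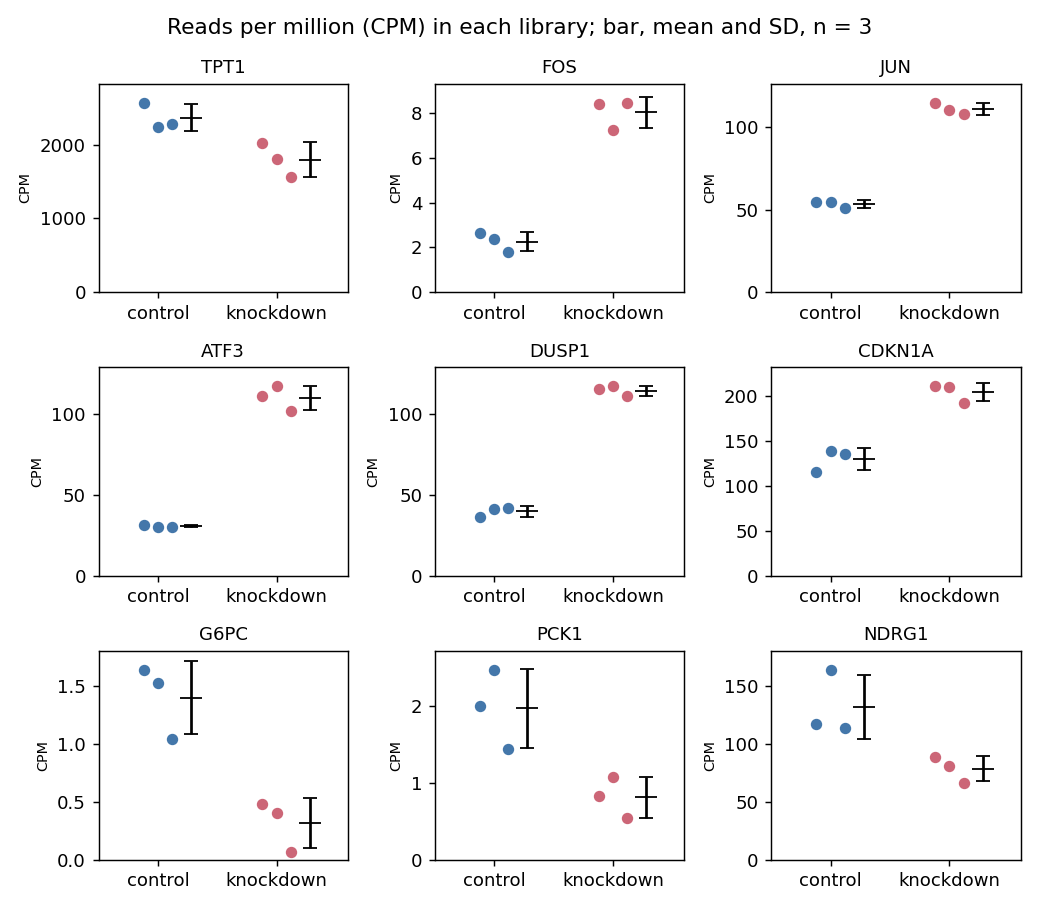
Points give CPM values of 9 genes in each of the 3 control (blue) and 3 knockdown (red) libraries, and the bars give mean and SD. The TPT1 values lay between 1559 and 2032 CPM in knockdown and between 2249 and 2575 CPM in control libraries.

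G6PC, the catalytic subunit that releases glucose from liver cells, fell from 1.40 ± 0.318 to 0.317 ± 0.219 CPM (SD, n = 3 each; log2 fold change -2.14, SE 0.46, edgeR adjusted p = 0.0292), on 29 to 50 reads in control and 2 to 14 in knockdown libraries. It missed the threshold without control library 1, control library 2 or knockdown library 2. Of 19 tested genes of gluconeogenesis and glycogen metabolism 0 rose and 1 fell (1 and 6 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 5.2e-06, and adjusted p = 0.0863 with an estimated correlation). PCK1, which makes phosphoenolpyruvate for glucose synthesis, stood at 1.97 ± 0.514 CPM in control and 0.813 ± 0.268 CPM in knockdown cells (SD, n = 3 each) and did not pass (edgeR adjusted p = 0.0719).

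Of 23 tested hypoxia-induced genes 0 rose and 3 fell (2 and 10 adjusted over the list alone), with a median of -0.39. They were LOX, CA9 and NDRG1 (log2 fold change -0.75), and the list had a camera adjusted p = 4.0e-06 and an adjusted p = 0.201 with an estimated correlation. LOX missed the threshold without control library 1 or 2, CA9 without control library 1 or 2 or knockdown library 1, and NDRG1 without control library 1 or 2 or knockdown library 2. Of 24 tested genes of cholesterol synthesis none passed over all genes and 7 were lower adjusted over the list alone, with a median of -0.28 (camera adjusted p = 4.0e-06, and adjusted p = 0.153 with an estimated correlation). LSS, which closes the sterol ring, had a log2 fold change of -0.47 (SE 0.13) and did not pass. Of 22 tested genes of glycolysis 0 passed (1 higher and 3 lower adjusted over the list alone), with a median of -0.26 (camera adjusted p = 8.9e-05, and adjusted p = 0.243 with an estimated correlation), ALDOC and PFKFB4 both standing at -0.65. Without knockdown library 3, 3 genes of cholesterol synthesis and 2 of gluconeogenesis were lower and 1 of glycolysis was higher. Of the hypoxia-induced genes 1 was then higher and 3 were lower. With the length or the GC correction 1 gene of gluconeogenesis was higher and 2 were lower, and 2 of cholesterol synthesis were lower.

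Hepatocyte identity genes had a median of -0.25 with 0 of 28 past the threshold (camera adjusted p = 0.000121, and adjusted p = 0.153 with an estimated correlation), FGA at -0.49 and TTR at -0.50. Acute phase genes had a median of -0.22, and 1 of 18, the iron hormone gene HAMP (-0.76), fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.00407, and adjusted p = 0.153 with an estimated correlation). Genes of lipoprotein assembly had a median of -0.19, and 1 of 20, MTTP (-0.66), which loads lipid onto apolipoprotein B, fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.179 with an estimated correlation). That list's camera adjusted p was 0.0836 without knockdown library 3. HAMP and MTTP each missed the threshold without any 1 control library or knockdown library 2. Genes of fatty acid oxidation had a median of -0.17 with 0 of 20 past the threshold, both over all genes and adjusted over the list alone (camera adjusted p = 0.00736, and adjusted p = 0.153 with an estimated correlation), FABP1 at -0.75 and ANGPTL4 at -0.79. Genes of fatty acid synthesis had a median of -0.17 with 0 of 20 past the threshold (camera adjusted p = 0.00298, and adjusted p = 0.201 with an estimated correlation), ACSS2 at -0.51 and FADS2 at -0.39. Hepatokine and IGF genes had a median of -0.11 with 0 of 23 past the threshold (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0217, and adjusted p = 0.179 with an estimated correlation), GDF15 at 0.56 and IGFBP1 at -0.56. Its camera adjusted p was 0.0763 without knockdown library 3. The hepatokine median was -0.22 without knockdown library 1, that of fatty acid synthesis -0.27 without knockdown library 3, that of fatty acid oxidation -0.11 without control library 1 and that of lipoprotein assembly -0.11 without knockdown library 3. Without knockdown library 1, 3 genes of lipoprotein assembly and 1 of fatty acid oxidation were lower, and the length correction also gave 3 for lipoprotein assembly. Without control library 1, 1 gene of fatty acid synthesis was lower, and without knockdown library 3, 1 hepatokine gene was higher.

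Components of insulin signalling themselves showed no shift in 1 direction that passed. Of 35 tested members 0 passed over all genes or adjusted over the list alone, the median was 0.07 (-0.01 without knockdown library 3) and the camera adjusted p was 0.458, with GRB10 at 0.47 and SH2B2 at -0.82. By limma's fry test the list did not pass for 1 direction (adjusted p = 0.785) but passed for differences in either direction (adjusted p = 0.0197), which compares it with no other genes. INSR, the insulin receptor, stood at 14.4 ± 1.47 and 13.8 ± 1.50 CPM (SD, n = 3 each; log2 fold change -0.06, edgeR adjusted p = 0.929). IRS1 had a log2 fold change of 0.35 (SE 0.18), AKT2 of -0.25 (SE 0.13), FASN of -0.06 (SE 0.22) and SREBF1 of 0.05 (SE 0.21), and none passed. The signs for INSR, FASN and SREBF1 turned under other settings. IRS2 had 1 to 6 reads per library and was not tested. In the RHEB and mTORC1 list 1 of 27 rose, SESN2 (2 and 0 adjusted over the list alone; camera adjusted p = 0.174).

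All 13 mitochondrially encoded messages had negative log2 fold changes with a median of -0.41, and 1 fell, both over all genes and adjusted over the list alone. It was MT-ATP8 (-0.75), whose reading frame overlaps MT-ATP6, and it missed the threshold without any 1 library but knockdown library 3. Reads of mitochondrial genes made up 10.84%, 8.71% and 10.35% of control libraries 1 to 3 and 8.43%, 8.61% and 6.63% of knockdown libraries 1 to 3. Mitochondrial ribosomal RNA made up 1.83% of knockdown library 3 against 3.52% to 4.48% of the other 5 libraries. The list of mitochondrial messages had a camera adjusted p = 2.7e-07 and an adjusted p = 0.195 with an estimated correlation. It passed camera with any 1 library left out, with a median of -0.33 without knockdown library 3 (camera adjusted p = 2.6e-05). Of 74 ribosomal protein genes 0 passed, RPL9 standing at -0.43 and RPL21 at -0.39, and the median of -0.15 (camera adjusted p = 3.1e-05, and adjusted p = 0.585 with an estimated correlation) became 0.04 (camera adjusted p = 0.472) without knockdown library 3. Of 42 nuclear genes of oxidative phosphorylation 0 passed, UQCRC2 standing at -0.31 and UQCRB at -0.39, and the median of -0.10 (camera adjusted p = 0.0125, and adjusted p = 0.585 with an estimated correlation) became 0.03 (camera adjusted p = 0.738) without knockdown library 3. Without control library 3 its camera adjusted p was 0.176. Small and structural noncoding RNAs had a median of -0.20 with 0 of 15 past the threshold (camera adjusted p = 0.0256, and adjusted p = 0.476 with an estimated correlation), SNORD3A at -0.80 and RMRP at -0.69, and the camera adjusted p was 0.278 without knockdown library 3 and 0.115 and 0.0539 without control library 1 or 2. It was 0.0846 with the filter of 1 CPM in 3 libraries and 0.0595 with the GC correction. The noncoding median was -0.57 without knockdown library 2, -0.42 without control library 3, -0.33 without control library 1 and -0.11 without knockdown library 3. S phase genes had a median of -0.11 with 0 of 29 past the threshold (camera adjusted p = 0.0101, and adjusted p = 0.153 with an estimated correlation), RFC4 at -0.48 and PCNA at -0.38. Its camera adjusted p was 0.0503 without knockdown library 2. In these lists, and in any other with 0 past the threshold and no second count given, none passed adjusted over the list alone either.

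Markers of other cell types were low or mixed. Of 11 leukocyte markers 1 rose, ITGAM (1.54), and 1 fell, AIF1 (-2.21), both with group means below 2 CPM and the same adjusted over the list alone. The leukocyte list had a median of -0.39 (camera adjusted p = 0.00394, and adjusted p = 0.195 with an estimated correlation). Of 5 squamous and kidney markers 1 rose, the keratin gene KRT17 (1.07; 2 and 0 adjusted over the list alone; camera adjusted p = 0.0194, and adjusted p = 0.179 with an estimated correlation). Of 2 tested endothelial and stellate markers 1 rose, LYVE1 (1.05; the same adjusted over the list alone; camera adjusted p = 0.0652), and of 5 fibroblast markers 0 passed (camera adjusted p = 0.479), with COL1A1 at 1.20 and S100A4 at -0.26. ITGAM and AIF1 missed the threshold without any library but knockdown library 3, KRT17 without control library 1 or 3, and LYVE1 without control library 1 or 2, with edgeR adjusted p of up to 0.193, 0.226, 0.121 and 0.0769. The endothelial and stellate list passed camera without control library 3 (adjusted p = 0.0417), without knockdown library 3 (0.00959) and with the filter of 1 CPM in 3 libraries (0.00328), which left 1 member, and its median ranged from 0.25 to 0.75 with 1 library left out. With that filter the leukocyte list did not pass (camera adjusted p = 0.111). The leukocyte median was -0.24 without knockdown library 3, and the fibroblast median of 0.11 was -0.02 without it. The camera adjusted p of the squamous and kidney list was 0.101 and 0.0622 without knockdown library 1 or 2.

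Of 21 interferon-stimulated genes 1 rose, OASL (1.77; the same adjusted over the list alone), and the median was -0.12 while the mean was 0.05 (camera adjusted p = 0.284, direction down). Without control library 3 the interferon median was -0.02. Of 13 bile acid and xenobiotic genes 1 rose, CYP1A1, a target of the aryl hydrocarbon receptor, from 53.2 ± 6.90 to 158 ± 24.4 CPM (SD, n = 3 each), while the list median was -0.23 (1 and 1 adjusted over the list alone; camera adjusted p = 0.0519). This list passed camera without knockdown library 1 (adjusted p = 0.0147) or 2 (0.0342) and with the GC correction (0.0442). None passed among 29 mitotic genes (camera adjusted p = 0.32; CCNB1 -0.28, CDC25C -0.41), 22 genes of the unfolded protein response (0.708; HSPA5 -0.27, EDEM1 0.32), 19 heat shock genes (0.437; BAG3 0.37, HSPD1 -0.38), 25 NRF2 targets (0.708; SRXN1 0.36, OSGIN1 0.34) and 33 translation factors (0.437; EIF5B 0.28, EIF3C -0.34). For the unfolded protein response the median was 0.02 (-0.10 without knockdown library 3) and the mean -0.01, and for NRF2 targets they were -0.001 and 0.04.

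Over the 35 lists, 24 passed camera with a preset correlation, 8 up and 16 down. Some lists share members, such as ALDOC and PFKFB4 in those of glycolysis and hypoxia, so the 24 are not separate results. With an estimated correlation 0 lists passed. A higher correlation was not the only reason, since the estimate lay below the preset 0.01 for the NF-kappaB list (-0.015) and the p53 list (-0.033). Their unadjusted camera p still went from 8.4e-09 to 0.0034 and from 9.3e-06 to 0.0074. Elsewhere the estimate reached 0.86, for ribosomal proteins. With an estimated correlation camera takes its degrees of freedom from the few libraries rather than the many genes, so it has less power here. That 0 passed therefore does not show that no list shifted. By limma's fry test, which asks whether a list's genes move one way without comparing them with other genes, 11 passed. Its version for differences in either direction passed for 21 lists, among them 4 that did not pass camera, those of insulin signalling, RHEB and mTORC1, interferon-stimulated genes, and bile acid and xenobiotic genes.

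**Figure D3:**
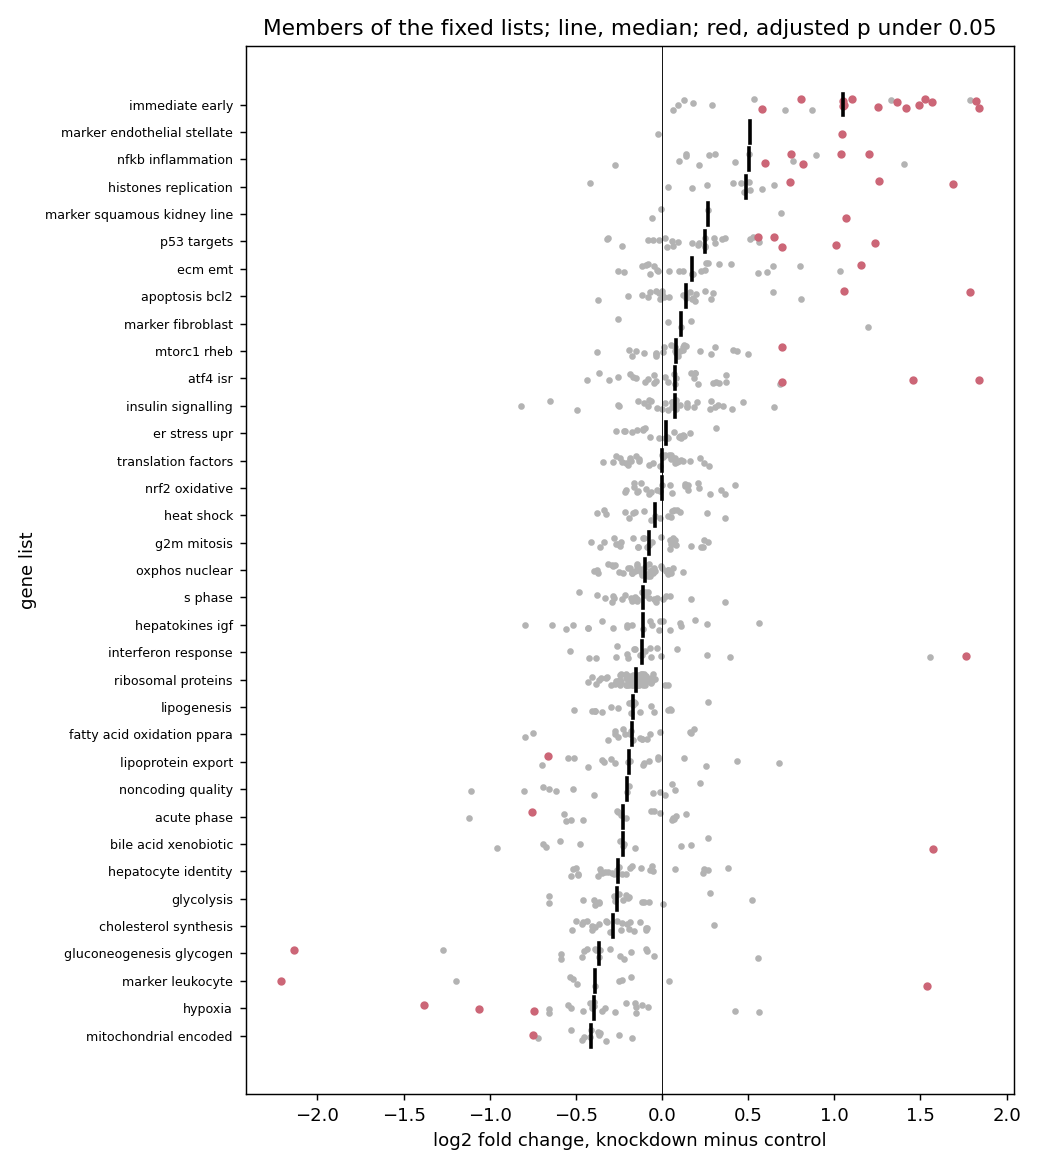
Each point is a tested member of 1 of the 35 fixed gene lists, placed by its log2 fold change, knockdown minus control, and the vertical line marks the list's median. Red points had an edgeR adjusted p under 0.05, and the immediate early list had the largest median, 1.05.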

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

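The corrections for gene length and GC content were chosen after seeing the data, and causes were not tested unless named. The 200 changed genes became 317 with no filter on low counts, where more genes were tested, 43 (42 higher, 1 lower) against a fold of 1.5, and 17 (17 higher, 0 lower) on unfiltered log2(FPKM + 1), where 1596 genes had an unadjusted p under 0.05. With the replicate number as a block 130 changed (111 higher), and the bile acid and xenobiotic list passed camera (adjusted p = 0.0188). The numbers were checked after each group's mean was taken out of every gene. The remaining values of samples with the same number correlated at -0.23, 0.001 and -0.20. No control sample correlated best with the knockdown sample of its own number. With 3 libraries per group the check is weak, and the numbers were not taken to pair the samples. Leaving out 1 library gave 79 to 343 changed genes, 76 to 300 higher, 3 to 43 lower and 63 to 155 changed at least 2-fold. The 21 lower genes became 71 with no filter, 58 with DESeq2, 7 and 9 on log2(FPKM + 1) and log2(FPKM + 0.1), 38 with the length and 36 with the GC correction. The 105 genes changed at least 2-fold became 44 on log2(FPKM + 1), where the pseudocount shrinks folds of low genes, 16 without its filter and 43 against a fold of 1.5. The 24 lists past camera became 0 with an estimated correlation, 11 by fry and 21 by fry in either direction. TPT1 stayed lower and short of the threshold under all 19 alternatives. INSR turned to 0.025 on log2(FPKM + 1), with or without the filter, and 0.036 on log2(FPKM + 0.1), and ranged from -0.14 to 0.019 with a library left out (0.009 and 0.019 without knockdown or control library 1). FASN turned to 0.018, with or without the filter, and 0.017 on those scales, and to 0.12 and 0.18 without control or knockdown library 1. SREBF1 turned to -0.13 and -0.18 without control or knockdown library 2, in a range of -0.18 to 0.27. Without knockdown library 3 the ribosomal protein median turned to 0.045, in a range from -0.32, and that of oxidative phosphorylation to 0.026, in a range from -0.22. IRS2, with 1 to 6 reads per library, had too few reads to test. INSIG1, of the cholesterol synthesis list, had 0 to 3 reads per library and was not tested either. The reason was not examined, so few reads in these counts need not mean low expression.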

Other observations

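Tests of the immediate early list and of GH1 were chosen after the results were seen, and so were the genes named in the next 2 sentences, for which no list was fixed and no enrichment was tested. The cytokine gene IL11 rose from 72.2 ± 0.977 to 193 ± 30.9 CPM, LIF from 20.7 ± 1.61 to 49.6 ± 2.88 CPM and CLCF1 from 8.67 ± 0.989 to 27.6 ± 1.20 CPM (SD, n = 3 each). The growth factor gene HBEGF rose 1.23 on the log2 scale, the receptor gene EPHA2 1.04, the GTPase genes RRAD 1.43 and RND1 1.62, the actin-binding CNN1 1.65 and the chaperone HSPB8 1.71, all past the edgeR threshold.

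ANKRD1 (log2 fold change 1.72), CYR61 (1.15) and AMOTL2 (1.12), known targets of the YAP and TEAD transcription factors, were among the genes that rose. The hypothesis that other targets rose too was written before their values were seen, although members shared with the fixed lists were known not to have passed. Without those 3, 4 of 18 tested targets rose, against 172 of 14176 other genes (one-sided Fisher exact p = 6.1e-05), namely MYOF (1.40), NUAK2 (0.82), AJUBA (0.60) and AXL (0.67). The Fisher test treats genes as independent draws, which genes measured in the same 6 libraries are not. With 1 library left out, a check chosen after seeing the data, the count of targets that rose changed. It was 0 without any 1 control library (Fisher p = 1) and 1 without knockdown library 2 (p = 0.093). It was 3 without knockdown library 1 and 5 without knockdown library 3. Without control library 1, 2 or 3 the log2 fold changes stayed positive, at 1.597, 1.477 and 1.148 for MYOF and 0.81, 0.84 and 0.79 for NUAK2. They were 0.62, 0.58 and 0.59 for AJUBA and 0.71, 0.78 and 0.53 for AXL. Calls of higher genes fell from 179 to 84, 76 and 87 in these fits, which have less power. The lost calls therefore do not show that the rise rested on 1 control library. CTGF, a leading target, stood at -0.26 and did not pass, several of these genes also respond to other stimuli, and whether YAP targets share a response stayed open.

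The rise of the immediate early list does not follow a length trend, since its median stayed at 1.04 after the length correction. An interferon response to transfected nucleic acid would raise most interferon-stimulated genes, and their upper quartile was -0.0048, although OASL rose. A difference in plasmid load or handling cannot be told apart from loss of TCTP, because 1 hairpin was compared with 1 control, TPT1 stood at 75.9% of control, and GH1, with a log2 fold change of 1.87, is the only gene here that might report plasmid load.

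GH1 rose although HepG2 is a liver line. Other genes of the growth hormone cluster held 0.027% as many reads as GH1, which argues against shared reads. The tested neighbours within 100 kb reached a log2 fold change of at most 0.083, which argues against activation that reaches them. All lay far from GH1, which starts at position 63917200, and the nearest, SMARCD2, ended at 63843065. Nearer genes, among them CD79B with 0 to 16 and SCN4A with 0 to 2 reads per library, had too few reads to test. Activation of the stretch close to GH1 therefore stayed open. Transcripts of a plasmid with a growth hormone polyadenylation cassette may account for the log2 fold change of 1.87. This cannot be told apart from expression of the gene, because reads per exon were not analysed here and the vector is not named.

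Knockdown library 3 stood apart, and its deviation from the others rose with gene length (Spearman rho 0.378 across 14075 genes, which are not independent replicates). Such trends were not particular to it, with a rho of -0.363 in control library 3 and 0.229 in control library 1. Its mean correlation with the others was 0.9774 after thinning to equal depth, which argues against depth as the whole cause. It was 0.9795 after the length correction, still below the 0.9867 of the next library, which argues against the length trend as the whole cause. Its RNA makeup differed too, with 96.8% protein-coding reads against 94.3% to 95.2% and 1.83% mitochondrial ribosomal RNA against 3.52% to 4.48%, but what sets it apart stayed open and no biological explanation was tested.

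Of the 10 ways to split the 6 libraries into 3 and 3, only the real one, 1 of 10, gave 200 genes by edgeR, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.1. Every other split mixes knockdown and control libraries in both of its groups. A real difference would then widen the spread within those groups and lower the count, so the other splits do not show what would be called without a difference. The other splits reached up to 1630 genes at an unadjusted p under 0.05, against 1572 for the real split, and limma voom gave 166 for the real split and 0 for every other.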
